A study of Mus musculus with 21 samples.

How the data were processed

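Total RNA from whole tibialis anterior muscle of male C57BL/6 mice aged 8 weeks was extracted with Trizol, labelled with biotin and measured on Affymetrix Mouse Gene 1.0 ST arrays, 1 array per sample. The deposited values are intensities per probe set that the authors made with RMA (background correction, quantile normalization and summarization) in Affymetrix Power Tools, per the submitters' processing notes. Versions and the probe set definition are not given in the sources used here. The table held 24922 probe sets in 21 samples, with values on a linear scale, and log2 was taken here. No 2 samples held identical values. Median intensity per array was 133.05 to 159.53, and the number of arrays limits the precision.

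Groups came from the sample titles, which give genotype (DTR+ or DTR-), CTx or xINJ, and day. DTR- day 4 xINJ replicate 1 carries a time tag of 8d while its title and its description of the preparation say day 4. It was used at day 4, and at day 8 as an alternative. DTR+ at day 0 and DTR+ xINJ at day 4 have 1 sample each and entered no comparison. With 3 against 3 or 2 against 3 samples the smallest two-sided exact permutation p is 0.1, so limma, which borrows the spread from all genes, was used throughout.

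Probe sets were joined to genes by the probe annotation of the array. It lists 22824 of them, leaves 2098 with no listed gene, gives 1399 several symbols and gives 21425 a single symbol. These stand for 19752 genes, and for the 921 genes with more than 1 probe set the one with the highest mean over all samples was used. The gene identifiers of 21347 probe sets were in the reference gene table, which changed 0 symbols. No genome was used and no coordinates are given. A gene was tested if it lay above the 40th percentile of its array (log2 6.62 to 6.84) on at least 2 arrays, which left 13278 genes. Where the dimmer group of a comparison lay below that level on every array, a fold is given as at least the brighter mean over the mean level of those arrays, which is not a limit of detection. In CTx against xINJ muscle this holds for Mki67, Top2a and Ccr2 in DTR- mice at day 4, Ms4a7, Adgre1 and Mki67 at day 8, and Cd3g and Gzmb in DTR+ mice. It also holds for Mx1 over the days in DTR- CTx muscle and for Mgl2 and Nkg7 with the genotype in xINJ muscle. Their log2 values in the text are the fitted ones, against background, as are those of Cd8a in CTx against xINJ muscle in DTR- mice, which did not pass.

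All 21 samples entered 1 limma fit (limma 3.58.1 in R 4.3.3) with a mean per group, 9 groups, 12 residual degrees of freedom and 6.56 prior degrees of freedom from eBayes with its defaults. The 11 contrasts were the genotype in CTx muscle at day 4, in CTx muscle at day 8 and in xINJ muscle at day 8, the difference between the days and between CTx and xINJ muscle of that effect, CTx against xINJ muscle in DTR- mice at each day and in DTR+ mice at day 8, and day 8 against day 4 in CTx muscle of each genotype and in xINJ muscle of DTR- mice. Tests were two-sided, with Benjamini-Hochberg adjustment within a contrast and a threshold of 0.05. Fold changes are DTR+ over DTR-, CTx over xINJ, or day 8 over day 4.

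For gene groups, 27 lists with 598 entries, of which 549 matched a gene in the table, were drawn from general knowledge of muscle repair, Tregs and the cell types of whole muscle, not from these samples. The immune lists were Treg, T cell, NK and cytotoxic Th1, interferon gamma induced, type I interferon induced, MHC class II, dendritic cell, inflammatory monocyte, repair macrophage, pan macrophage, neutrophil, eosinophil and type 2, and B cell. The others were myogenic, mature fast fibre, slow fibre, glycolysis, mitochondrial respiration, fatty acid oxidation, proliferation, extracellular matrix, fibroadipogenic progenitor, adipocyte, endothelial, nerve and Schwann cell, erythroid, and atrophy and denervation. Each was tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. Unless another test is named, list p-values in the text are from camera with an estimated correlation. The preset correlation and fry each called lists that it did not call. Members were also counted after adjustment over the list alone. The lists, the contrasts, the tests and the rule for named genes were chosen before the data were examined.

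Genes named in the text are, per contrast, up to 6 with the largest positive and up to 6 with the largest negative log2 fold change among those that passed and whose groups did not overlap (for a difference of effects, that passed), up to 4 members of each list with the smallest p, and a fixed set with Foxp3, Il2ra, Ctla4, Il10, Klrg1, Ifng, Gzmb, Cxcl9, Cd3e, Cd8a, Adgre1, Ccr2, Mrc1, Pax7, Myod1, Myog, Myh3, Myh4, Ckm, Col1a1 and Mki67. Where none passed in a direction, the rule took the 3 with the smallest p. Areg and Spp1 were in the fixed set and are not analysed here.

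Whether samples with the same replicate number belong together was checked by correlating their deviations from the group means over genes. In CTx muscle at day 8 the 3 pairs of DTR+ and DTR- samples had r from 0.23 to 0.55, and in DTR- CTx muscle the 3 pairs of day 8 and day 4 samples had r from 0.24 to 0.35, with every sample closest to its own number. These pairs were counted as paired by this check alone, since they differ in genotype or day and cannot be the same muscle. The main fit used no block, so its p-values, counts and list tests ignore this pairing, which entered only as an alternative. With the number as a replicate block, 638 genes passed for the genotype in CTx muscle at day 8 and 4635 for day 8 against day 4 in DTR- CTx muscle, and no call of a named gene or list in these 2 contrasts was lost. No other 2 groups had 3 pairs that all passed an r of 0.1, and groups with 2 pairs were not counted as paired.

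The fit was tested on simulated data with the groups, spread and 13278 genes of the real table. Genes were simulated independently, and in each comparison 67, 67 and 66 of them were changed by 1.5-fold, 2-fold and 4-fold. With fewer changed genes the adjustment asks for a smaller p, and the shares would be lower. For the genotype in CTx muscle at day 8, 34.3% of changes of 1.5-fold, 86.6% of 2-fold and 98.5% of 4-fold were called, with 9 unchanged genes called. For the genotype in CTx muscle at day 4 the shares were 28.4%, 65.7% and 97.0%, with 5 unchanged genes called, and for the genotype in xINJ muscle at day 8 they were 29.9%, 70.1% and 97.0%, with 5.

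Alternatives, each changing 1 choice, were quantile normalization again, centring each array on its median, no filter, a filter at the 60th percentile, low values raised to the 20th percentile, the mean of all probe sets of a gene, eBayes with trend and robust options, array weights, only the groups of the contrast, the replicate number as a block, a fold threshold of 1.5 beside the adjusted p, the tagged sample at day 8, and each sample left out in turn. For CTx against xINJ muscle and for the difference between them, the replicate block joined samples of the same genotype, day and number. This treats such samples as from 1 animal, which the labels do not say. A plain replicate number as a block and the removal of 2 doubted samples were added after the data were seen. Where leaving out a sample left a group with 1, that sample was assumed to vary like the other groups.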

Results

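Whole tibialis anterior muscle, a muscle of the lower leg, was profiled on 21 expression arrays. The mice were Foxp3-DTR+, in which diphtheria toxin is meant to remove Foxp3-expressing regulatory T cells (Tregs), or Foxp3-DTR- mice given the same toxin. Cardiotoxin, a snake venom toxin that kills muscle fibres and spares their stem cells, had been injected at day 0, and muscle was taken at day 4 or day 8. Sample titles divide the muscles into CTx and xINJ, and the other labels describe both as injured with cardiotoxin, so xINJ is used here only as the title's name for a group. Within each genotype and day, every xINJ sample correlated more with the DTR+ day 0 sample than every CTx sample did. DTR- mice gave 3 CTx samples and 3 xINJ samples at each day. DTR+ mice gave 2 CTx samples at day 4, 3 CTx samples at day 8, 1 xINJ sample at day 4, 2 xINJ samples at day 8 and 1 sample at day 0. Median intensity per array lay between 133.05 and 159.53, and the number of arrays limits the precision. The labels do not say that the samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

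The first question was whether the transcript of the targeted cells could be followed. Foxp3, the transcription factor that defines Tregs, had a log2 intensity between 6.27 and 6.95 in every sample, close to the level below which genes were not tested. In CTx muscle at day 4 its mean was 6.40 ± 0.09 (SD, n = 3) in DTR- mice and 6.39 ± 0.17 (SD, n = 2) in DTR+ mice. In CTx muscle at day 8 it was 6.64 ± 0.22 (SD, n = 3) in DTR- mice and 6.46 ± 0.22 (SD, n = 3) in DTR+ mice, a log2 fold change of -0.18 with a limma adjusted p of 0.72. In xINJ muscle at day 8 it was 6.73 ± 0.19 (SD, n = 3) in DTR- mice and 6.67 ± 0.02 (SD, n = 2) in DTR+ mice. The loss of Tregs was therefore not measurable from Foxp3 in these arrays, and the comparisons below are between genotypes as labelled. Of other genes used to describe Tregs, Il2ra, Ctla4, Il10 and Klrg1 lay below the filter. Tested without the filter, in DTR+ CTx muscle at day 8 Il2ra, the interleukin 2 receptor alpha chain, was higher by 0.79 (limma adjusted p = 0.025) and Ctla4, an inhibitory receptor, by 0.59 (limma adjusted p = 0.044), both of which other activated T cells also make. Klrg1 (0.53, limma adjusted p = 0.14) and Il10 (-0.08) did not pass.

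CTx or xINJ in the title, and the day, went with the largest differences between samples. The first principal component held 62.0% of the variance over 13278 tested genes and placed CTx muscle at day 4, CTx muscle at day 8 and the xINJ and day 0 muscles in that order without overlap. The second held 9.0%.

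The comparison of CTx with xINJ muscle in DTR- mice at day 4 asked what distinguished the kinds of muscle at the earlier day. CTx muscle held the transcripts of regenerating fibres, macrophages and matrix, and less of those of mature fibres. Myh3, the embryonic myosin heavy chain, was 24.9-fold higher (log2 fold change 4.64 ± 0.44, SE, 3 against 3, limma adjusted p = 1.03e-07). The log2 fold change was 5.43 without replicate 1 of DTR- xINJ day 4, the sample of doubtful day, and 4.02 without replicate 3. Mymk, which fuses myoblasts, rose by 4.21, Chrng, the fetal subunit of the acetylcholine receptor, by 4.11, and Myog, a factor of myoblast differentiation, by 3.71. Adgre1, which encodes the macrophage marker F4/80, rose by 3.60 from 7.40 ± 0.28 to 11.01 ± 0.27 (SD, n = 3 each).

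All 22 tested pan macrophage genes rose (median log2 fold change 3.17), among them Ms4a7 (4.59), Mpeg1 (4.43), Cybb (4.08), a subunit of the phagocyte oxidase, and Csf1r (3.10), the receptor for macrophage growth factor. Of 33 myogenic genes, 27 rose and 1 fell (median 1.77). Those 2 lists held their camera call with an estimated correlation (adjusted p = 0.029 for each). Repair macrophage genes gave 18 that rose and 2 that fell of 22, with Gpnmb at 3.76 and Mrc1 at 2.28 (adjusted p = 0.052 with an estimated correlation). Every one of the 9 MHC class II genes rose (median 2.43, adjusted p = 0.064 with an estimated correlation), H2-Ab1 by 2.84. So did all 23 type I interferon induced genes (median 2.04, adjusted p = 0.116 with an estimated correlation), Irf7 by 3.25 and Oasl2 by 2.73. The interferon gamma induced list had 16 of 19 higher (17 adjusted over the list alone, median 1.31, adjusted p = 0.203 with an estimated correlation), and its chemokine Cxcl9 rose by 2.33. Inflammatory monocyte genes rose for 13 of 18 (14 adjusted over the list alone) and 1 fell, with Ccr2, the receptor that brings monocytes into tissue, at 3.00 (adjusted p = 0.137 with an estimated correlation). Neutrophil genes rose for 4 of 6 and dendritic cell genes for 8 of 12 (adjusted p = 0.064 and 0.099 with an estimated correlation). Extracellular matrix genes rose for 34 of 37 (median 1.61, adjusted p = 0.064 with an estimated correlation), Timp1 by 3.26 and Col1a1 by 1.53, and proliferation genes for 26 of 28 (median 1.56, adjusted p = 0.118 with an estimated correlation), Mki67 by 2.84 and Top2a by 2.44. Pax7, the factor that marks muscle stem cells, rose by 0.83.

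Genes of the mature fibre were lower in the same comparison. Of 27 fast fibre genes 23 fell and 1 rose (24 and 1 adjusted over the list alone, median -0.86, adjusted p = 0.137 with an estimated correlation). The one that rose, Mybph (2.17), encodes a myosin binding protein. Glycolysis genes fell for 19 of 20 and rose for 1 (median -1.21, adjusted p = 0.153 with an estimated correlation). Mitochondrial respiration genes fell for 46 of 49 (median -0.90, adjusted p = 0.072 with an estimated correlation), with Cox7a1 at -1.83, and fatty acid oxidation genes fell for 18 of 20 (19 adjusted over the list alone, median -1.04, adjusted p = 0.130 with an estimated correlation), with Decr1 at -1.41. Single genes with the largest decreases were Scn4b (-3.30), a sodium channel subunit, Mlf1 (-3.08), Plcd4 (-3.07), Rpl3l (-2.97), a ribosomal protein of striated muscle, and Phkg1 (-2.96), a subunit of the kinase that starts glycogen breakdown. Ckm, muscle creatine kinase, changed by -0.84 (-0.54 without DTR- CTx day 4 replicate 1) and Myh4, the fast IIB myosin, fell by 0.82. DTR- CTx day 4 replicate 1 stood apart, with Ckm at 12.52 where the other samples of its group had 13.37 and 13.50, and a fast fibre list mean of 11.68 against 12.28 and 12.42. Slow fibre genes went both ways, with 8 of 12 higher and 3 lower (Tnni1 3.67). Endothelial genes fell for 10 of 17, with Kdr, a receptor for vascular growth factor, at -1.26, adipocyte genes for 5 of 13 and red blood cell genes for all 4. T cell genes rose for 3 of 13 and fell for 1, NK and cytotoxic Th1 genes rose for 7 of 14 and fell for 1, and Cd3e (0.30) and Cd8a (0.06) did not pass. Fibroadipogenic progenitor genes rose for 6 of 18 and fell for 3, atrophy and denervation genes rose for 5 of 15 and fell for 6, and B cell genes rose for 2 of 4. Nerve and Schwann cell genes rose for 2 of 9 and fell for 1, and 1 rose and 1 fell among 12 Treg genes (Ebi3 was higher by 1.03) and among 9 eosinophil and type 2 genes. In the nerve list and the eosinophil list the median and the mean or test differed in sign.

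The count was 6190 of 13278 genes, 3472 higher and 2718 lower in CTx muscle. The split depended on scaling, because group medians differed. Centring each array on its median moved the median log2 fold change by -0.19 and gave 2679 higher and 4735 lower, and quantile normalization gave 2988 and 3712. Without DTR- CTx day 4 replicate 1 and the xINJ sample of doubtful day, set aside after the data were seen, 4954 genes passed.

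At day 8 the same comparison in DTR- mice asked what remained of this state. Regenerating fibre, macrophage and matrix genes were still higher, and fast fibre and energy genes were mostly not called. Postn, a matrix protein of healing tissue, was highest, 14.4-fold higher in CTx muscle (log2 fold change 3.85 ± 0.39, SE, 3 against 3, limma adjusted p = 1.21e-06). Myh3 was still 13.5-fold higher (3.76 ± 0.44, limma adjusted p = 8.15e-06), and Mymk rose by 3.41, Igf2, a fetal growth factor, by 3.14, and Myog by 2.78. Pan macrophage genes rose for 20 of 22 (22 adjusted over the list alone, median 2.14), with Ms4a7 at 3.51, Cybb at 2.96 and Adgre1 at 2.56. Myogenic genes rose for 24 of 33 (27 adjusted over the list alone, median 1.29), extracellular matrix genes for 32 of 37 (33 adjusted over the list alone, median 1.17, Col1a1 2.19), MHC class II genes for 7 of 9 (median 2.17, H2-Ab1 2.67) and slow fibre genes for 8 of 12 (median 1.28, Tnni1 3.67). Repair macrophage genes rose for 10 of 22 and fell for 1 (12 and 1 adjusted over the list alone, median 0.69, Mrc1 1.17). These 6 lists held with an estimated correlation, at adjusted p between 0.0025 and 0.043. Type I interferon induced genes rose for 15 of 23 (21 adjusted over the list alone, adjusted p = 0.189 with an estimated correlation), interferon gamma induced genes for 9 of 19 (10 adjusted over the list alone, Cxcl9 1.64, adjusted p = 0.388 with an estimated correlation) and proliferation genes for 10 of 28 (14 adjusted over the list alone, Mki67 1.10, adjusted p = 0.421 with an estimated correlation). Fatty acid oxidation genes fell for 5 of 20 (10 adjusted over the list alone, adjusted p = 0.222 with an estimated correlation), and Lpl, which releases fatty acids from lipoproteins, fell by 1.01. Ces1d (-2.43), Inmt (-2.17) and Nqo1 (-1.88), enzymes of lipid and xenobiotic metabolism, had the largest decreases, and none of the 49 mitochondrial genes passed. Ckm (-0.10), Myh4 (-0.15), Pax7 (0.26), Cd3e (0.20) and Cd8a (0.12) did not pass. In all 1799 genes passed, 1378 higher and 421 lower. Centring moved the median by -0.13 and gave 1039 higher and 1003 lower, quantile normalization gave 1267 and 804, and 1026 genes passed without DTR- CTx day 8 replicate 3, of which 156 were lower. Lower genes were 228 without replicate 1 of that group, and 227 and 250 without replicates 1 and 3 of DTR- xINJ day 8.

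In DTR+ mice at day 8 the same comparison asked how the 2 kinds of muscle differed in the other genotype. Postn (4.28), Tnni1 (3.72), Myh3 (3.61), Myog (3.32) and Ncam1 (3.10), an adhesion molecule of regenerating and denervated fibres, were higher in CTx muscle. Lymphocyte transcripts were higher as well, with Nkg7 at 2.32, Cd3g at 2.07, Gzmb at 1.73 and Cd8a at 1.33. T cell genes rose for 12 of 13 (median 1.14, adjusted p = 0.084 with an estimated correlation), and NK and cytotoxic Th1 genes for 12 of 14 (13 adjusted over the list alone, median 1.01, adjusted p = 0.120 with an estimated correlation). Pan macrophage genes rose for 21 of 22 (median 2.24), myogenic genes for 27 of 33 (30 adjusted over the list alone, median 1.51), matrix genes for 32 of 37 (median 1.46), repair macrophage genes for 16 of 22 with 1 lower (17 and 1 adjusted over the list alone, median 1.19), MHC class II genes for 7 of 9 (8 adjusted over the list alone, median 2.12) and slow fibre genes for 8 of 12 (median 1.81). These 6 lists held with an estimated correlation, at adjusted p between 0.013 and 0.041. Interferon gamma induced genes rose for 4 of 19 and fell for 3, and type I interferon induced genes rose for 4 of 23 (5 adjusted over the list alone) and fell for 2, Ifit3 by a log2 fold change of -2.12 (-1.37 without DTR+ xINJ day 8 replicate 1). Atrophy and denervation genes fell for 9 of 15 and rose for 1 (median -0.87, adjusted p = 0.127 with an estimated correlation), and Depp1 (-2.92), Slc40a1 (-2.87), the cellular iron exporter, Klhl38 (-2.50) and Bnip3 (-2.01), a mitophagy receptor, were among the largest decreases. Of 3353 genes that passed, 2223 were higher and 1130 lower. Centring moved the median by -0.18 and gave 1591 higher and 2134 lower, quantile normalization gave 2002 and 1739, and 1833 genes passed without DTR+ xINJ day 8 replicate 1, of which 554 were lower. Without replicate 2 of that group 655 were lower. The calls at day 8 in the 2 genotypes overlapped in 1182 higher genes, where independent lists would share 230.7, and in 338 lower genes, where they would share 35.8, and 4 genes were called in opposite directions.

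The change from day 4 to day 8 in CTx muscle of DTR- mice described the course of repair in that genotype. Receptor subunits exchanged, with Chrng, the fetal form, lower with a log2 fold change of -2.75 ± 0.20 (SE, 3 against 3, limma adjusted p = 7.74e-08) and Chrne, the adult form, higher by 2.42 ± 0.27 (limma adjusted p = 3.56e-06). Myh3 changed by -2.14, Myog by -1.25 and Pax7 by -0.69 (-0.44 without DTR- CTx day 4 replicate 2), while Myh2, the fast IIA myosin, rose by 2.76. Macrophage and interferon transcripts fell, with Ms4a6d at -2.75, Ccr2 at -2.04, Csf1r at -2.03, Adgre1 at -1.95 and Mx1, an antiviral GTPase, at -1.86. All 22 pan macrophage genes fell (median -1.82), 15 of 22 repair macrophage genes fell (17 fell and 1 rose adjusted over the list alone, median -0.90) and 4 of 6 neutrophil genes fell (median -1.19), and these 3 lists held with an estimated correlation at adjusted p = 0.049. Type I interferon induced genes fell for 22 of 23 (23 adjusted over the list alone, median -1.19, adjusted p = 0.111 with an estimated correlation), proliferation genes for 26 of 28 (27 adjusted over the list alone, median -1.22, Mki67 -1.55, adjusted p = 0.108 with an estimated correlation) and matrix genes for 24 of 37 with 1 higher (25 adjusted over the list alone, median -0.84, adjusted p = 0.108 with an estimated correlation). Myogenic genes fell for 20 of 33 and rose for 3 (22 and 4 adjusted over the list alone, adjusted p = 0.108 with an estimated correlation). Mature fibre genes rose, with 23 of 27 fast fibre genes higher (25 adjusted over the list alone, median 0.80, Tnni2 1.14, adjusted p = 0.108 with an estimated correlation), 19 of 20 glycolysis genes higher and 1 lower (median 0.99, adjusted p = 0.111 with an estimated correlation), and 42 of 49 mitochondrial genes higher (43 adjusted over the list alone, median 0.74, Cox7a1 1.53, adjusted p = 0.068 with an estimated correlation). Interferon gamma induced genes fell for 7 of 19 and none rose, and Cxcl9 (-0.69, limma adjusted p = 0.084), Cd3e (0.05) and Col1a1 (-0.43) did not pass. Of 3937 genes, 1544 were higher and 2393 lower at day 8. Centring moved the median by 0.11 and gave 2487 higher and 1993 lower. Higher genes were 995 without DTR- CTx day 4 replicate 1.

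In CTx muscle of DTR+ mice the same change included increases in immune genes. Rnase2a, a ribonuclease of the eosinophil-associated family, was at least 9.43-fold higher, from below the filter level on every array at day 4. Retnla, secreted by macrophages under type 2 cytokines, rose by 3.57, Iigp1, an interferon-induced GTPase, by 2.70, Arg1, the arginase of such macrophages, by 2.30 from below that level, and Cd2, a T cell adhesion molecule, by 1.09. Interferon gamma induced genes rose for 9 of 19 (14 adjusted over the list alone, median 0.73, adjusted p = 0.146 with an estimated correlation), NK and cytotoxic Th1 genes for 8 of 14 (11 adjusted over the list alone, median 0.64, adjusted p = 0.146 with an estimated correlation) and T cell genes for 5 of 13 (8 adjusted over the list alone, median 0.59, adjusted p = 0.161 with an estimated correlation). Chrng changed by -2.53 and Adgre1 by -1.08, pan macrophage genes fell for 12 of 22 (18 adjusted over the list alone, median -0.83, adjusted p = 0.146 with an estimated correlation), matrix genes for 19 of 37 (28 adjusted over the list alone, median -0.75, adjusted p = 0.146 with an estimated correlation) and proliferation genes for 13 of 28 (22 adjusted over the list alone, adjusted p = 0.161 with an estimated correlation). Fast fibre genes rose for 11 of 27 (12 adjusted over the list alone, median 0.39, adjusted p = 0.165 with an estimated correlation) and mitochondrial genes for 12 of 49 (28 adjusted over the list alone, median 0.48, adjusted p = 0.146 with an estimated correlation). Myog (-0.15, limma adjusted p = 0.70), Mrc1 (-0.15) and Ckm (0.20) did not pass. The count was 1471 genes, 377 higher and 1094 lower, against 636 and 907 with centred arrays and 600 and 995 with quantile normalization. Without DTR+ CTx day 4 replicate 2 it was 624, of which 112 were higher, and without DTR+ CTx day 8 replicate 1 it was 973.

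In xINJ muscle of DTR- mice few genes differed between the days. Lyz2, the macrophage lysozyme, had a log2 fold change of -1.07, Fstl1 of -1.06 and Sparc, a matrix protein, of -0.76, and Nmrk2 (-1.62) and Cep85l (1.57) had the largest changes. Adjusted over the list alone, 14 of 22 pan macrophage genes (median -0.62), 21 of 37 matrix genes (median -0.55) and 4 of 18 fibroadipogenic progenitor genes (median -0.41) fell, against 1, 1 and 2 over all genes tested, and these 3 lists held with an estimated correlation at adjusted p = 0.015. An unadjusted p under 0.05 was held by 633 genes, fewer than a share of 0.05 of those tested. That number was 1274 and 375 without replicates 1 and 2 of day 4, and 1746 with the tagged sample at day 8. In total 9 genes passed after adjustment, 1 higher and 8 lower. None of the named gene calls was kept in every leave-one-out, with adjusted p up to 0.352. The count was 0 without replicate 1 or 2 of day 4 or replicate 2 of day 8, 2 without replicate 3 of day 4 or replicate 1 of day 8, and 5 without replicate 3 of day 8.

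The comparison of DTR+ with DTR- mice in CTx muscle at day 4 asked whether the genotypes differed early. Gm4841 was 5.84-fold higher in DTR+ muscle, at 9.66 ± 0.39 (SD, n = 2) against 7.12 ± 0.27 (SD, n = 3), a log2 fold change of 2.55 ± 0.30 (SE, limma adjusted p = 0.0010). An unadjusted p under 0.05 was held by 274 genes, fewer than a share of 0.05, so this fit shows no excess of small p. That number was 83 without DTR- CTx day 4 replicate 1 and 749 without replicate 2. Gm4841 was the 1 gene of 13278 that passed after adjustment. Without DTR+ CTx day 4 replicate 2 the count was 5, of which 1 was higher and 4 lower. Over all genes Cd3g (limma adjusted p = 0.30), which lay below the filter level on every DTR- array, and Nkg7 (1.23) did not pass. Adjusted over the list alone, 5 of 13 T cell genes rose (median 0.40, adjusted p = 0.154 with an estimated correlation), and of 14 NK and cytotoxic Th1 genes 4 rose and 1 fell (median 0.27, adjusted p = 0.297 with an estimated correlation). Adjusted in the same way, 4 of 23 type I interferon induced genes fell (median -0.49, adjusted p = 0.124 with an estimated correlation), with Irf7 at -1.06 not passing over all genes, and 1 MHC class II gene and 1 neutrophil gene fell. Regeneration genes Myog (-0.04), Myh3 (-0.20), Mki67 (-0.18) and Col1a1 (0.00) did not pass. At the preset correlation 14 lists were called, among them glycolysis (median 0.42) and fast fibre genes (median 0.30) higher. No list held with an estimated correlation, at adjusted p of 0.188 and 0.244 for these 2, and for the MHC class II and myogenic lists the median and the mean or test differed in sign. On simulated data with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold, 65.7% of 2-fold and 97.0% of 4-fold changes were called. With 1 gene called here the adjustment asked for a smaller p, so these shares do not apply to single genes of this comparison.

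At day 8 the comparison of the genotypes in CTx muscle asked how they differed later. DTR+ muscle held more of the transcripts of T cells, cytotoxic lymphocytes, interferon gamma responses, antigen presentation and macrophages. Retnla was 21.7-fold higher (log2 fold change 4.44 ± 0.39, SE, 3 against 3, limma adjusted p = 2.40e-06). Rnase2a was at least 9.25-fold higher (limma adjusted p = 2.28e-08), at 9.94 ± 0.92 against 4.40 ± 0.29 (SD, n = 3 each), the latter below the filter level on every array. Myog was 2.08-fold higher, at 10.30 ± 0.26 against 9.25 ± 0.21 (SD, n = 3 each, limma adjusted p = 0.0026), while Myh3 did not pass (0.12, limma adjusted p = 0.97).

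Of 19 interferon gamma induced genes 18 rose (19 adjusted over the list alone, median 1.61). They included Iigp1 (3.21), Irgm1 (2.26), the chemokine Cxcl9 (2.24 ± 0.29, SE, limma adjusted p = 9.71e-05), which attracts activated T cells, and Tap1 (1.88) and Psmb8 (1.61), which prepare peptides for MHC class I. Gm12185 rose by 4.10, and it lay above the filter level on 1 of 3 DTR- arrays. In DTR- muscle Cd8a, Cd3g, Cd8b1, Cd2, Gzmb, Cxcr6, Ifng, Ccl22, Clec9a, Chil3, Arg1, Ccl24 and Icos also lay below the filter level on every array, so the sizes given for them are against background. Among T cell genes 10 of 13 rose (12 adjusted over the list alone, median 0.80), with Cd3g at 2.14, Cd8b1 at 1.78, Cd8a, the coreceptor of cytotoxic T cells, at 1.61 ± 0.20 (SE, limma adjusted p = 5.69e-05), Cd3e at 1.46 and Cd2 at 1.44. NK and cytotoxic Th1 genes rose for 10 of 14 (13 adjusted over the list alone, median 1.06), with Nkg7 at 2.49, Cxcr6 at 2.09, Gzmb, a protease of cytotoxic granules, at 2.07 and Ccl5 at 2.07. Ifng itself rose by 0.65, and its adjusted p was 0.053 and 0.090 without DTR+ replicates 2 and 3 and 0.111 and 0.104 without DTR- replicates 1 and 2 of that day. MHC class II genes rose for 7 of 9 (8 adjusted over the list alone, median 1.30), with H2-Ab1 at 1.32, H2-Aa at 1.30 and Ciita, their transcriptional activator, at 1.25. These 4 lists held with an estimated correlation (adjusted p = 0.0050, 0.0050, 0.0053 and 0.0050).

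Pan macrophage genes rose for 11 of 22 (17 adjusted over the list alone, median 0.85, adjusted p = 0.0091 with an estimated correlation), among them Fcgr3 (1.36), Cybb (1.24), Csf1r (1.17) and the complement gene C1qb (1.00). Repair macrophage genes rose for 5 of 22 (9 adjusted over the list alone, median 0.42, adjusted p = 0.0053 with an estimated correlation), led by Retnla, Arg1 (2.48), Mgl2 (1.95) and Mrc1 (1.13). Ccl8, a monocyte chemokine, rose by 2.85 and Mmp12, the macrophage elastase, by 1.72. Inflammatory monocyte genes rose for 5 of 18 (6 adjusted over the list alone, median 0.42, adjusted p = 0.154 with an estimated correlation), with Chil3 at 2.49. Dendritic cell genes rose for 3 of 12 (4 adjusted over the list alone, median 0.25), Itgax by 1.93, Ccl22 by 1.33 and Clec9a by 1.02, and eosinophil and type 2 genes for 2 of 9 (median 0.31), Ccl24 by 1.42 and Ccl11 by 1.21. Both held with an estimated correlation (adjusted p = 0.038 and 0.014). Without DTR+ CTx day 8 replicate 3 their medians were 0.14 and 0.15, and the eosinophil median was 0.47 without DTR+ replicate 1 and 0.14 without DTR- replicate 1. Treg genes rose for 4 of 12 (median 0.18, adjusted p = 0.038 with an estimated correlation). Icos (1.19) and Tigit (0.93) are receptors that other activated T cells also carry. The list's preset call was lost under a stricter filter on low values, at an adjusted p of 0.085. Type I interferon induced genes rose for 2 of 23 (3 adjusted over the list alone, median 0.05, adjusted p = 0.757 with an estimated correlation), with Zbp1 at 1.09. Neutrophil genes rose for 1 of 6 and B cell genes for 0 of 4 (1 adjusted over the list alone).

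Few of the muscle's own genes passed. Of 33 myogenic genes 2 rose, Myog among them (2 rose and 1 fell adjusted over the list alone, median 0.12), and Myod1 (0.41) and Pax7 (0.00) did not pass. None of 27 fast fibre genes (median -0.15), 20 glycolysis genes (median -0.23), 49 mitochondrial genes (median -0.17), 28 proliferation genes (median 0.21), 13 adipocyte genes, 9 nerve and Schwann cell genes or 4 red blood cell genes passed, with Ckm at -0.12, Myh4 at -0.48 and Mki67 at 0.50. At the preset correlation the fast fibre, glycolysis and mitochondrial lists were called lower and the proliferation list higher, with adjusted p of 0.517, 0.367, 0.353 and 0.371 with an estimated correlation. Matrix genes went both ways, with 3 of 37 higher and 1 lower (4 and 2 adjusted over the list alone). The one that fell was Lum (-1.21), a proteoglycan that orders collagen fibrils. Fibroadipogenic progenitor genes rose for 1 of 18 and fell for 1. Fatty acid oxidation genes fell for 1 of 20 (3 adjusted over the list alone, median -0.23), slow fibre genes rose for 1 of 12 and atrophy and denervation genes for 1 of 15. Endothelial genes fell for 2 of 17 (6 adjusted over the list alone, median -0.37, adjusted p = 0.305 with an estimated correlation). The 2 that fell were Kdr (-0.93) and Cdh5 (-0.88), the cadherin of endothelial junctions. Outside that list, Aplnr, the apelin receptor, and Map2k6, a kinase upstream of p38, each changed by -1.52. The call of Kdr was lost without DTR+ replicate 2 or 3 or DTR- replicate 1 or 3 of CTx day 8, at adjusted p of 0.116, 0.052, 0.095 and 0.090, and that of Cdh5 without any 1 of the 6 samples, at adjusted p from 0.068 to 0.204.

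In all 489 of 13278 genes passed, 402 higher and 87 lower in DTR+ muscle. The split was 404 higher and 135 lower with centred arrays and 424 and 135 with quantile normalization. The count was 265 without DTR+ replicate 3, 276 without DTR- replicate 1 and 290 without DTR- replicate 2 of CTx day 8. Those counts held 29, 26 and 27 lower genes, and 52 genes were lower without DTR+ replicate 1, 67 without DTR+ replicate 2 and 34 without DTR- replicate 3.

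**Figure D1:**
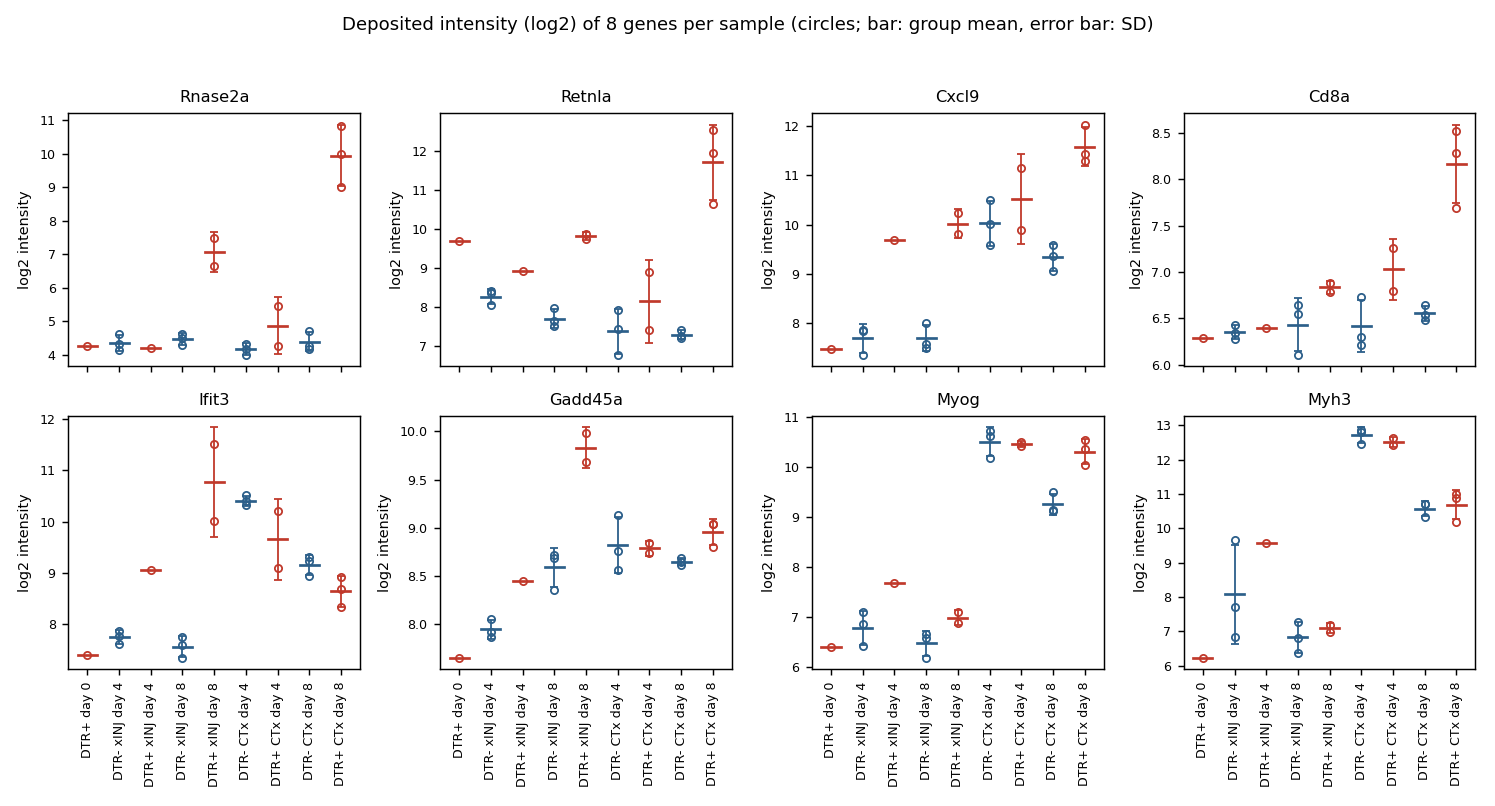
Log2 intensity (vertical axis) of 8 genes in the groups of samples (horizontal axis), with a circle per sample, a bar at the group mean, an error bar of 1 SD, DTR+ in red and DTR- in blue. Rnase2a averaged 9.94 in DTR+ and 4.40, below the filter level, in DTR- CTx muscle at day 8, while Ifit3 averaged 10.76 in DTR+ and 7.56 in DTR- xINJ muscle at day 8.

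Whether the genotype acted differently at the 2 days in CTx muscle was tested directly as the difference of the effects. It was larger at day 8 for Retnla (by 3.66, limma adjusted p = 0.0066), Itgax (by 1.75) and Mgl2 (by 1.72). It was also larger for Rnase2a (limma adjusted p = 1.57e-04), Arg1 and Ccl24, which lay below the filter level on every array of the other 3 CTx groups, so their fitted differences do not measure size. These calls were kept in every leave-one-out, while that of Ccl24 was at 0.051 with only the groups of the contrast in the fit. Other genes with a larger effect were Ccl8 (3.07), Tap1 (1.69) and Psmb8 (1.58), whose adjusted p rose to 0.111, 0.174 and 0.102 without DTR+ CTx day 4 replicate 3. Among the 4 genes with a lower effect at day 8, Mylk4 (-2.83), a kinase of the myosin light chain kinase family, had adjusted p of 0.291 without that sample, 0.067 without DTR+ CTx day 8 replicate 3 and 0.080 without DTR- CTx day 8 replicate 2. Differences for Cd8a (limma adjusted p = 0.15) and Gzmb (limma adjusted p = 0.14), both below the filter level in DTR- muscle at day 8, Cd3e (0.73, limma adjusted p = 0.43) and Myog (1.10, limma adjusted p = 0.091) did not pass. As lists, the interferon gamma induced genes (6 of 19 over all genes and 18 adjusted over the list alone, median 1.58, adjusted p = 0.013 with an estimated correlation), MHC class II genes (3 of 9 and 8 adjusted over the list alone, median 1.13, adjusted p = 0.011 with an estimated correlation), pan macrophage genes (4 of 22 and 14 adjusted over the list alone, median 0.95, adjusted p = 0.013 with an estimated correlation) and NK and cytotoxic Th1 genes (1 of 14 and 11 adjusted over the list alone, median 1.08, adjusted p = 0.035 with an estimated correlation) had the larger effect at day 8. T cell genes had 0 of 13 (6 adjusted over the list alone, median 0.66, adjusted p = 0.050 with an estimated correlation). An unadjusted p under 0.05 was held by 1381 genes, by 909 without DTR- CTx day 4 replicate 1 and by 1677 without replicate 2. The count after adjustment was 78 genes, 74 with a higher and 4 with a lower effect at day 8. Centred arrays gave 75 and 15, and the replicate number as a block gave 138 and 15, a count of 153. The count was 12 without DTR+ CTx day 4 replicate 3 and 223, of which 58 were lower, without DTR+ CTx day 4 replicate 2. Of the DTR- CTx day 4 samples, it was 28 without replicate 1, 103 (32 lower) without replicate 2 and 153 (22 lower) without replicate 3. Of the DTR+ CTx day 8 samples, it was 138, 46 and 35 without replicates 1, 2 and 3, and of the DTR- CTx day 8 samples 26, 31 and 47.

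**Figure D2:**
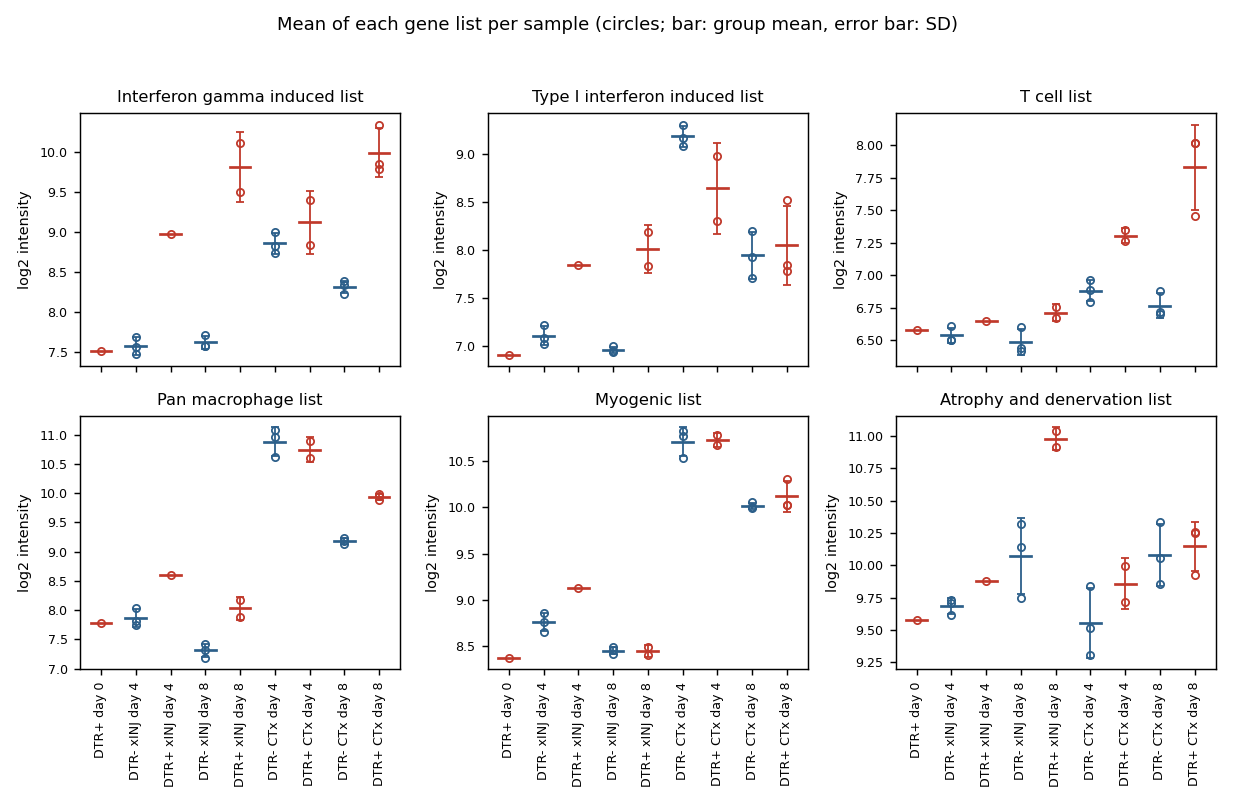
Mean log2 intensity (vertical axis) of the tested genes of 6 lists in the groups of samples (horizontal axis), with a circle per sample, a bar at the group mean, an error bar of 1 SD, DTR+ in red and DTR- in blue. The interferon gamma induced list averaged 9.99 in DTR+ and 8.31 in DTR- CTx muscle at day 8, and 9.80 and 7.62 in xINJ muscle at day 8.

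The comparison of the genotypes in xINJ muscle at day 8 asked the same question of the other kind of muscle. DTR+ muscle held far more interferon-induced transcripts. Irgm1, a GTPase that defends against pathogens inside cells, was 15.1-fold higher (log2 fold change 3.92 ± 0.28, SE, 2 against 3, limma adjusted p = 3.11e-07), and Iigp1 was 25-fold higher (4.64 ± 0.43, limma adjusted p = 2.92e-06), from 7.51 ± 0.33 (SD, n = 3) to 12.15 ± 0.84 (SD, n = 2). Its log2 fold change was 4.05 and 5.23 without replicates 1 and 2 of DTR+ xINJ day 8. Gadd45a, which rises in denervated and wasting muscle, was 2.36-fold higher (1.24 ± 0.17, limma adjusted p = 3.51e-04). No single T cell gene passed, with Cd3e at 0.39 (limma adjusted p = 0.61) and Cd8a, below the filter level on every DTR- array, at an adjusted p of 0.52. As a list, T cell genes were called higher at the preset correlation (11 of 13 above 0, median 0.26, adjusted p = 0.027) and not with an estimated correlation (adjusted p = 0.461).

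Interferon gamma induced genes rose for 16 of 19 (17 adjusted over the list alone, median 2.25, adjusted p = 0.0054 with an estimated correlation), with Cd274, the ligand PD-L1, at 4.16, Gbp7 at 3.99, Tap1 at 2.68 and Cxcl9 at 2.32 beside Irgm1. Gm12250 (4.02) was among the largest increases, and Gm12185 was at least 10.4-fold higher, from below the filter level on every DTR- array. Type I interferon induced genes rose for 11 of 23 (12 adjusted over the list alone, median 0.71). Their adjusted p was 0.075 in camera with an estimated correlation, 5.24e-21 at the preset correlation and 0.0078 with fry. Ifit3 rose by 3.20 ± 0.33 (SE, limma adjusted p = 1.28e-05). Ifit1 (2.56), Irf7 (1.93) and Usp18 (1.87) had adjusted p of 0.067, 0.054 and 0.054 without DTR+ xINJ day 8 replicate 1. MHC class II genes rose for 5 of 9 (7 adjusted over the list alone, median 1.20, adjusted p = 0.019 with an estimated correlation), H2-Ab1 by 1.68 and H2-Aa by 1.60, and pan macrophage genes for 9 of 22 (16 adjusted over the list alone, median 0.77, adjusted p = 0.033 with an estimated correlation), Mpeg1 by 1.74, Cybb by 1.39 and C1qb by 1.18. Atrophy and denervation genes rose for 7 of 15 (11 adjusted over the list alone, median 0.92, adjusted p = 0.034 with an estimated correlation). Beside Gadd45a, Mt1 (1.64), which encodes a metallothionein, stood at 1.05 with an adjusted p of 0.213 without DTR+ xINJ day 8 replicate 2.

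NK and cytotoxic Th1 genes rose for 3 of 14 (median 0.24, adjusted p = 0.303 with an estimated correlation), of which Nkg7 (1.53) had an adjusted p of 0.224 without DTR+ xINJ day 8 replicate 2 and 0.067 without DTR- xINJ day 8 replicate 3. None of 13 T cell genes, 12 Treg genes, 12 dendritic cell genes or 9 eosinophil and type 2 genes passed, and Ifng and Gzmb, below the filter level on every array of both genotypes, did not. Repair macrophage genes rose for 2 of 22 (4 adjusted over the list alone, adjusted p = 0.198 with an estimated correlation), where Retnla (2.12) had adjusted p of 0.110 and 0.109 without DTR+ xINJ day 8 replicates 1 and 2 and Mgl2 (1.26) had 0.062 without replicate 2. Matrix genes rose for 1 of 37 and fell for 2 (1 and 6 adjusted over the list alone, median -0.22, adjusted p = 0.461 with an estimated correlation), with Lum at -1.23 and an adjusted p of 0.171 without DTR+ xINJ day 8 replicate 1, and fibroadipogenic progenitor genes fell for 2 of 18 (median -0.30, adjusted p = 0.131 with an estimated correlation). Of the muscle's own genes, 1 of 33 myogenic genes rose and 1 fell, 1 of 27 fast fibre genes fell, 2 of 20 glycolysis genes fell and 0 of 49 mitochondrial genes passed. The fast fibre, glycolysis and mitochondrial lists were called lower at the preset correlation, with medians of -0.11, -0.34 and -0.24, and had adjusted p of 0.557, 0.387 and 0.303 with an estimated correlation. Inflammatory monocyte genes (median 0.18) and endothelial genes (median -0.25) lost their preset calls in the same way, at adjusted p of 0.461 and 0.570. Nrep (-2.45), Itgb6 (-1.77), an integrin subunit, and Sema6c (-1.77), a semaphorin, had the largest decreases kept in every leave-one-out. For the Treg, eosinophil, myogenic and fatty acid oxidation lists the median and the mean or test differed in sign.

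In all 347 genes passed, 240 higher and 107 lower in DTR+ muscle. The excess of higher genes depended on 1 sample, since without replicate 2 of DTR- xINJ day 8 there were 213 higher and 224 lower. The count was 90 and 153 without replicates 1 and 2 of DTR+ xINJ day 8 (13 and 32 lower), and 183 and 133 without replicates 1 and 3 of DTR- xINJ day 8 (30 and 20 lower). With 1 DTR- sample titled day 4 but tagged 8d moved to day 8, it was 602, 349 higher and 253 lower. The genes called in CTx and in xINJ muscle at day 8 shared 85 higher genes, where independent lists would share 7.27, and 16 lower genes, where they would share 0.70, and 0 were called in opposite directions. Across the 13278 genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.518.

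**Figure D3:**
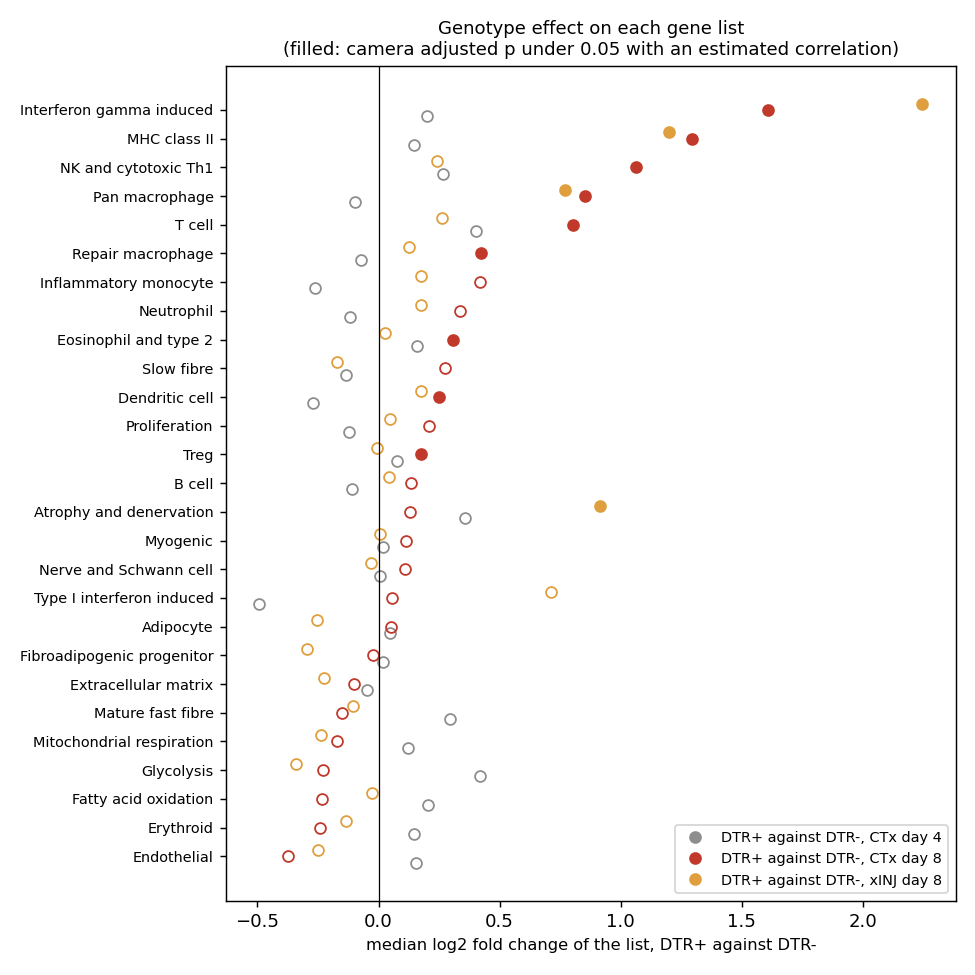
Median log2 fold change of DTR+ against DTR- (horizontal axis) of each gene list (vertical axis) in CTx muscle at day 4 (grey), CTx muscle at day 8 (red) and xINJ muscle at day 8 (orange), filled where the list's adjusted p with an estimated correlation was under 0.05. The interferon gamma induced list stood at 1.61 in CTx and 2.25 in xINJ muscle at day 8, and the T cell list at 0.80 and 0.26. Only 1 T cell gene lay above the filter level on every xINJ array of day 8, so the value of 0.26 is mostly from signal near background.

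Whether the genotype acted differently in CTx and xINJ muscle at day 8 was again tested as a difference of effects. The effect was larger in CTx muscle for Pdcd1lg2 (limma adjusted p = 1.24e-04), which encodes the ligand PD-L2 and lay below the filter level in every group but DTR+ CTx day 8, and Col6a5 (by 1.78, limma adjusted p = 0.0033), and larger in xINJ muscle for Ifit3 (-3.71, limma adjusted p = 6.46e-04) and Vegfd (-2.02, limma adjusted p = 0.0010), a lymphatic growth factor. These calls were kept in every leave-one-out. Itgax, Rnase2a, Chil3, Arg1 and Ifit1 (-2.90) also passed, at adjusted p of 0.112, 0.198, 0.121, 0.153 and 0.272 without DTR+ xINJ day 8 replicate 1. Of these, the calls other than that of Itgax were also lost without 1 or another of DTR+ xINJ day 8 replicate 2, DTR+ CTx day 8 replicates 1 and 2 and the DTR- samples of day 8, at adjusted p up to 0.099. Itgax, Rnase2a, Chil3 and Arg1 lay below the filter level on every DTR- xINJ array of day 8, so their fitted differences do not measure size. The same holds for Gzmb (limma adjusted p = 0.075) and Cd8a (limma adjusted p = 0.13), whose differences did not pass. Differences for Gadd45a (-0.93, limma adjusted p = 0.12) and Cxcl9 (-0.08) did not pass. Adjusted over the list alone, 10 of 13 T cell genes (median 0.81, adjusted p = 0.054 with an estimated correlation) and 8 of 14 NK and cytotoxic Th1 genes (median 0.78, adjusted p = 0.062 with an estimated correlation) had a larger effect in CTx muscle, against 0 and 0 over all genes tested. In the same way 7 of 23 type I interferon induced genes (2 over all genes, median -0.84, adjusted p = 0.109 with an estimated correlation) and 6 of 15 atrophy and denervation genes (0 over all genes, median -0.76, adjusted p = 0.062 with an estimated correlation) had a larger effect in xINJ muscle. Camera at the preset correlation called all of these lists, at adjusted p up to 1.12e-11. With fry the adjusted p was 0.017 for T cell, 0.042 for NK and cytotoxic Th1, 0.081 for type I interferon and 0.044 for atrophy genes. Only 1 of the 13 T cell genes lay above the filter level on every xINJ array of day 8. Signal near background can shrink the effect in xINJ muscle, so the difference of the T cell list does not measure size. For interferon gamma induced genes the difference was called only by camera at the preset correlation (median -0.35, adjusted p = 0.0014). Its adjusted p was 0.495 with an estimated correlation and 0.525 with fry. The count was 31 genes, 14 with a higher and 17 with a lower effect in CTx muscle, against 12 and 27 with centred arrays and 22 and 7 without replicate 1 of DTR+ CTx day 8, and 863 had an unadjusted p under 0.05. The count was 6 and 17 without replicates 1 and 2 of DTR+ xINJ day 8, 17 without replicate 2 of DTR+ CTx day 8, 14, 15 and 14 without replicates 1, 2 and 3 of DTR- CTx day 8, and 15 and 13 without replicates 1 and 3 of DTR- xINJ day 8. With the sample tagged 8d at day 8 it was 57.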

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

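The tests for 1 aberrant sample, for a ceiling of the arrays, for a level that CTx muscle does not exceed and for the smaller group at day 4 were chosen only after the results were seen.

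Differences of the genotype effect between day 8 and day 4 in CTx muscle passed in limma's test for 78 genes. Fitted differences were, in order, Rnase2a (4.86), Retnla (3.66), Ccl8 (3.07), Gm12185 (2.91), Arg1 (2.58) and Iigp1 (2.56), and in the other direction Mylk4 (-2.83), Ddit4l (-2.16), Plaat1 (-1.52) and Rcan2 (-1.24). Those of Rnase2a, Arg1 and Gm12185 do not measure size or rank. Rnase2a and Arg1 lay below the filter level on every array of the other 3 CTx groups, and Gm12185 lay above it on 0 of 3 DTR- arrays at day 4, 1 of 3 DTR- arrays at day 8 and 1 of 2 DTR+ arrays at day 4. Without DTR+ CTx day 4 replicate 3 the adjusted p was 0.111 for Ccl8, 0.174 for Gm12185, 0.445 for Iigp1, 0.291 for Mylk4, 0.409 for Ddit4l, 0.210 for Plaat1 and 0.291 for Rcan2, and 12 genes passed. The calls of Gm12185, Iigp1, Mylk4, Ddit4l, Plaat1 and Rcan2 were also lost without 1 or another of the DTR+ and DTR- CTx day 8 samples and DTR- CTx day 4 replicates 1 and 3, at adjusted p up to 0.129. Lists that differed had medians of 1.58 (interferon gamma induced), 1.13 (MHC class II), 1.08 (NK and cytotoxic Th1), 0.95 (pan macrophage), 0.70 (dendritic cell), 0.63 (neutrophil) and 0.46 (repair macrophage). For the neutrophil list the preset adjusted p was 0.052 without DTR+ CTx day 4 replicate 3.

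Differences of the genotype effect between CTx and xINJ muscle at day 8 passed for 31 genes. Fitted differences above 0 (CTx minus xINJ) were, in order, Rnase2a (2.95), Chil3 (2.45), Arg1 (2.07), Pdcd1lg2 (2.01), Itgb6 (1.82) and Col6a5 (1.78). That of Itgb6 came from a genotype effect of -1.77 in xINJ muscle beside 0.05 in CTx muscle. Rnase2a, Chil3, Arg1 and Pdcd1lg2 lay below the filter level on every array of both DTR- groups, so their values do not measure size or rank. Those below 0 were Ifit3 (-3.71), Ifit1 (-2.90), Vegfd (-2.02), Gclm (-1.89), D230025D16Rik (-1.65) and Ctxn3 (-1.60). Without DTR+ xINJ day 8 replicate 1 the adjusted p was 0.198 for Rnase2a, 0.121 for Chil3, 0.153 for Arg1, 0.198 for Itgb6, 0.272 for Ifit1, 0.198 for Gclm, 0.085 for D230025D16Rik and 0.080 for Ctxn3, and 6 genes passed. The calls of Rnase2a, Chil3, Arg1, Itgb6, Ifit1 and Gclm were also lost without 1 or another of the other day 8 samples, at adjusted p up to 0.123.

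The lone DTR+ xINJ sample at day 4, which no comparison used, lay above the 3 DTR- xINJ samples of that day by more than their range in the mean log2 intensity of 9 lists, which was not tested. Interferon gamma induced genes stood at 8.97 (7.47 to 7.69 in DTR-), type I interferon induced genes at 7.85 (7.02 to 7.22) and MHC class II genes at 8.88 (7.79 to 8.14). Pan macrophage genes stood at 8.59 (7.74 to 8.03), inflammatory monocyte genes at 6.52 (6.17 to 6.30), dendritic cell genes at 7.04 (6.84 to 6.90) and NK and cytotoxic Th1 genes at 6.50 (6.06 to 6.24). Myogenic genes stood at 9.13 (8.66 to 8.86) and atrophy and denervation genes at 9.88 (9.61 to 9.73). It lay below them by more than their range for glycolysis genes, at 12.01 (12.12 to 12.24).

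Interferon gamma induced genes were higher in xINJ muscle of DTR+ mice at day 8, where no T cell gene passed and the T cell list was called higher only at the preset correlation (adjusted p = 0.027, and 0.461 with an estimated correlation). Carry-over of RNA from CTx muscle is argued against, since the genes at least 2-fold higher in CTx than in xINJ muscle of DTR- mice at day 4 had a median log2 fold change of 0.090 in that comparison and an upper quartile of 0.31. A single aberrant sample is argued against, since the lower DTR+ sample lay 1.79 above the highest DTR- sample in the list mean, where the DTR- samples spanned 0.14. T cells in the muscle as the source stay open, because only 1 T cell gene, Thy1, lay above the filter level in every sample (0.079), too few for the test. A response of muscle or other cells to interferon from elsewhere may remain as a hypothesis and was not tested.

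Type I interferon induced genes rose with the genotype for 11 of 23 in xINJ muscle and for 2 of 23 in CTx muscle at day 8. A single aberrant sample is argued against by a gap of 0.83 between the lower DTR+ and the highest DTR- xINJ sample, against a range of 0.06. A ceiling of the arrays is argued against, since 22 of 23 genes were called higher at day 4 than at day 8 in CTx muscle of DTR- mice, so the arrays read higher levels. That CTx muscle had no room to rise because its level was already raised stays open. In DTR- CTx muscle at day 8, 12 of the 23 were at or above their level in DTR+ xINJ muscle. That is most of the list, which goes with this explanation by the rule set beforehand. All 12 of these were called higher in the same kind of muscle at day 4. This argues against a level that such muscle never exceeds, but does not show that there was room to rise at day 8. In DTR- CTx muscle the list mean was 9.18 at day 4 and 7.94 at day 8. A limit set by the cells present at day 8 was not tested and stays open. For this list the difference of the genotype effect between CTx and xINJ muscle was called by camera at the preset correlation (adjusted p = 7.07e-16). It was not called with an estimated correlation (adjusted p = 0.109) or by fry (adjusted p = 0.081).

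Few genes passed for the genotype in CTx muscle at day 4 and many at day 8. The smaller DTR+ group at day 4 alone is argued against, since day 8 without 1 DTR+ sample still gave at least 265 genes. A larger spread at day 4 that hid effects of the same size is argued against for the 402 genes higher at day 8, as a set. Their median log2 fold change was -0.0079 at day 4, with an upper quartile of 0.16, against 0.96 at day 8, where they were chosen. The median pooled SD was 0.22 at day 4 and 0.18 at day 8. The 2 DTR+ CTx day 4 arrays differed. The interferon gamma list had medians of 0.031 and 0.477 without replicates 2 and 3, so the day 4 values are uncertain. An effect of the genotype that grows between the days may be the reason, as a hypothesis, and the length of toxin treatment, which differs between the days by design, was not tested apart from it. The interferon gamma list mean went from 8.85 at day 4 to 8.31 at day 8 in DTR- CTx muscle. In DTR+ CTx muscle it went from 9.12 to 9.99, so both genotypes contributed to the larger difference at day 8.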

How the results depend on the processing

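The plain replicate number as a block and the removal of 2 doubted samples were chosen only after the data were seen. Signal near background limits Foxp3 and most lymphocyte genes of xINJ muscle, and groups of 2 or 3 arrays limit the counts, of which 36 of 72 moved by over 1.5 times when 1 sample was left out. Under the other alternatives 114 counts stayed within 1.5 times and 18 did not.

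Leave-one-out counts ran from 1 to 5 for the genotype in CTx muscle at day 4 (without DTR+ CTx day 4 replicates 3 and 2), from 265 to 515 in CTx muscle at day 8 (DTR+ replicates 3 and 1) and from 90 to 437 in xINJ muscle at day 8 (DTR+ replicate 1 and DTR- replicate 2). They ran from 12 to 223 for the difference between days (DTR+ CTx day 4 replicates 3 and 2) and from 6 to 31 for the difference between CTx and xINJ (DTR+ xINJ day 8 replicate 1 and DTR+ CTx day 8 replicate 3). For CTx against xINJ they ran from 1026 to 1551 in DTR- at day 8 (DTR- CTx replicate 3 and xINJ replicate 2) and from 1833 to 3132 in DTR+ (DTR+ xINJ and CTx replicates 1). For day 8 against day 4 they ran from 624 to 1637 in DTR+ CTx muscle (DTR+ CTx day 4 replicate 2 and day 8 replicate 3) and from 0 to 5 in DTR- xINJ muscle (DTR- xINJ day 4 replicate 1 and day 8 replicate 3). For day 4 DTR- CTx against xINJ and for day 8 against day 4 in DTR- CTx muscle no sample moved the count by 1.5 times.

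For the genotype in CTx muscle at day 4, the direction of the test turned for 6 lists when a sample was left out. Only lists called at the preset correlation with or without that sample were counted. In 4 of the 6 the median changed sign. For interferon gamma induced and MHC class II genes the medians stayed positive and the direction of the test turned, without DTR+ replicate 2 and DTR- replicate 1. None of these 6 lists held with an estimated correlation. Without DTR+ CTx day 4 replicates 2 and 3 the ends were 0.031 and 0.477 for interferon gamma induced genes, 0.035 and 0.226 for MHC class II genes (0.21 without DTR- CTx day 4 replicate 1), -0.58 and 0.012 for inflammatory monocyte genes, 0.28 and -0.039 for mitochondrial genes and -0.42 and 0.17 for proliferation genes (0.08 without DTR- CTx day 4 replicate 2). Pan macrophage genes ran from -0.23 without DTR- CTx day 4 replicate 3 to 0.005 without DTR+ CTx day 4 replicate 3. The neutrophil list in DTR+ CTx muscle, day 8 against day 4, had a median of 0.15 without the filter, which brings in genes at background.

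With array weights 1854 genes passed for the genotype in CTx muscle at day 8 (978 higher and 876 lower), 1682 in xINJ muscle (732 higher and 950 lower), 460 for the difference between CTx and xINJ, 4401 for CTx against xINJ in DTR- at day 8 and 2879 for day 8 against day 4 in DTR- xINJ muscle. The weights did not reach their convergence tolerance and gave 1 array a weight of 24.5. With only the groups of the contrast, which leaves fewer degrees of freedom, 26 passed for the difference between days, 841 for day 8 against day 4 in DTR+ CTx muscle and 0 in DTR- xINJ muscle. With the tagged sample at day 8, 602 passed for the genotype in xINJ muscle, 57 for the difference between CTx and xINJ and 0 for day 8 against day 4 in DTR- xINJ muscle. That last count was 2 with quantile normalization, 2 with centred arrays and 1 with trend and robust options, and the cause was not tested.

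With the replicate block the count was 153 for the difference between days, 54 for the difference between CTx and xINJ (55 with the plain number) and 20 for day 8 against day 4 in DTR- xINJ muscle. In the 2 paired contrasts it ended no call of a named gene or list. The difference between days joins those paired groups with DTR+ CTx day 4, of 2 samples, and there the block moved the preset adjusted p of slow fibre genes to 0.050. For the genotype in xINJ muscle it moved that p to 0.053 for T cell and 0.13 for inflammatory monocyte genes. In the difference between CTx and xINJ and in CTx against xINJ in DTR- at day 8 it ended 4 preset list calls and made 5. Same-numbered samples of the groups not counted as paired had r from -0.45 to 0.47. DTR+ CTx and xINJ muscle at day 8 had only 2 pairs, both higher (0.297 and 0.313) than any other r between them (up to 0.071), and the block gave 3346 genes there.

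Of the genes named and called in a contrast, 42 of 45 for the genotype in CTx muscle at day 8 and 18 of 26 in xINJ muscle were called in every leave-one-out, and 44 and 26 in every other setting. A setting that did not test a gene, as the stricter filter can, was left out for that gene. The 34 called for CTx against xINJ in DTR- at day 4 were called in every leave-one-out and every other setting. So were the 14 for day 8 against day 4 in DTR- CTx muscle. Calls were lost most in the differences of effects and in xINJ muscle over time. Of those named and called, 6 of 15 were called in every leave-one-out for the difference between days, 4 of 13 for the difference between CTx and xINJ and 0 of 5 for day 8 against day 4 in DTR- xINJ muscle. These named genes were picked partly for their small p, so the shares do not hold for all called genes.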

Other observations

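No test in this part was chosen only after its result was seen.

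The DTR+ sample of day 0, which entered no comparison, was set beside the other samples. A Pearson r with the day 0 sample was taken over 13278 genes, which are not independent replicates. It was 0.943 to 0.988 for the 9 xINJ samples and 0.770 to 0.950 for the 11 CTx samples. These ranges overlapped only between genotypes. Within each genotype and day every xINJ sample had a higher r than every CTx sample. In DTR- mice r was 0.953 to 0.988 against 0.770 to 0.834 at day 4, and 0.965 to 0.981 against 0.942 to 0.950 at day 8. In DTR+ mice at day 8 it was 0.943 and 0.945 against 0.870 to 0.901. Myh3, the embryonic myosin, was 6.24 at day 0, 9.67 in DTR- xINJ day 4 replicate 1, 9.58 in the DTR+ xINJ day 4 sample and 6.37 to 7.73 in the other xINJ samples. DTR- xINJ day 4 replicate 1 is also the sample whose time tag disagrees with its title. The myogenic list mean was 8.38 at day 0, and 8.45 in xINJ and 10.02 in CTx muscle of DTR- mice at day 8. For pan macrophage genes these means were 7.78, 7.31 and 9.18. At day 8 xINJ muscle of DTR- mice thus showed little of the regenerating state of CTx muscle. Whether it had been injected cannot be told from 1 day 0 sample.

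A hypothesis from Myog was that CTx muscle of DTR+ mice lagged in fibre regeneration at day 8. It would raise the myogenic genes that were higher in CTx than in xINJ muscle at day 4 and fell by day 8 in DTR- mice. Over these 20 genes the median log2 fold change of the genotype at day 8 was 0.14 and the upper quartile 0.22, under the bound of 0.3 set for a lag, with 15 of 20 positive and 1, Myog, called. For these 20 genes a lag of that size is therefore argued against, and a smaller one was not tested. Some other values went the way of a lag. Genotype log2 fold changes were above 0 for 5 of 27 fast fibre, 2 of 20 glycolysis and 6 of 49 mitochondrial genes. They were above 0 for 27 of 28 proliferation genes, though no such list held with an estimated correlation. On the first principal component these DTR+ samples lay at -28.84 to -19.13. DTR- CTx samples lay at -68.25 to -53.52 at day 4 and -7.41 to 0.03 at day 8. A lag outside these 20 genes stays open.

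A hypothesis from Rnase2a and Retnla was that eosinophils had entered CTx muscle of DTR+ mice at day 8. The markers Siglecf, Prg2, Epx, Ccr3 and Il5ra had a median log2 fold change of 0.071 without the filter, and their largest value plus 2 standard errors was 0.56. Prg2, Epx, Ccr3 and Il5ra lay below the filter level on every array and decide nothing. Siglecf lay above it on 19 arrays, close to it (means 6.91 and 6.85), and its log2 fold change was 0.055 (SE 0.13). That goes against eosinophils, but 1 marker near the floor does not exclude them, and the test leaves them open.

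There are 10 splits of the 6 samples into 3 and 3, the real one included, too few for a share under 0.05. In each of 5 contrasts only the real split, 1 of 10, gave as many genes. The real values were 489 for the genotype in CTx muscle at day 8, 6190 and 1799 for CTx against xINJ in DTR- mice at day 4 and day 8, and 3937 and 9 for day 8 against day 4 in DTR- CTx and xINJ muscle. The highest of the other splits was 0 in each. Every other split mixes the real groups, so a difference between those enters the spread within groups and lowers the count. These counts therefore decide nothing.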
